A study of Homo sapiens with 9 samples.

How the data were processed

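RNA-seq was analysed in 9 libraries of SW480 cells in 3 groups of 3: DMSO, LPS at 6 µg/ml, and LPS at 6 µg/ml with ILA at 200 µM, each after 6 h. Groups were taken from the sample titles and treatment labels. The titles of the third group name ILA alone, and its treatment label reads ILA+LPS. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. No pair of libraries held identical values.

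The authors deposited 1 table of TPM values with 2 decimals for the whole series. Per the submitters' processing notes the deposited TPM values were made with RSEM, and the version, the aligner and the annotation are not given in the sources used here. RSEM shares reads that fit several genes among them by probability, so genes with near-identical copies are uncertain. The notes list the build mm10, a mouse build, while all 34000 gene rows carry human Ensembl identifiers and 0 carry mouse ones, so the build behind the values is not known. The table used here is incomplete: gene rows are in ascending order of identifier, stop at the number 237236, and are followed by 24 lines of a web error page. The last 2 gene rows have no values, which left 33998 genes, 11697 of them at 0 in all libraries. TPM columns that list every gene sum to 1000000, and these sum to between 945885 and 947594. In GENCODE release 29, 24638 genes, 1705 of them protein-coding, have identifiers beyond the last one of the table and were not analysed here. TPM removes differences in depth, so the depth per library is unknown and no counting error can be given.

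Columns were matched to samples by name. The 3 ILA columns carry the numbers of the ILA titles. Columns named as negative carry the numbers 1, 2 and 4, which only the DMSO titles have, and columns named as positive carry 1, 2 and 3 and were matched to LPS. This last match is an inference from the names.

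TPM values are not counts, so the count model foreseen in the design was replaced by the branch the design held for normalized values. Values were transformed as log2(TPM + 1), with a pseudocount of 1. Genes with at least 1 TPM in at least 3 libraries were kept, which left 12902. One linear model with the 3 groups was fitted to all 9 libraries with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend, and the 3 contrasts were tested with Benjamini-Hochberg adjustment over all genes at 0.05. There were 6 residual degrees of freedom, and the median standard error of a log2 fold change was 0.15. A fold change on the log2(TPM + 1) scale understates the change of low genes. Means and SDs are of TPM over 3 libraries.

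The 37 gene lists were fixed before the data were examined, as were the groups, the design, the first set of alternatives and the rule for named genes. Of these, 34 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 34 lists. Camera passed 13 lists in LPS against DMSO, 16 in ILA+LPS against LPS and 11 in ILA+LPS against DMSO, with an estimated correlation 3, 0 and 2, and fry 3, 1 and 4. The rule named, in each comparison, up to 8 genes with the largest rise and up to 8 with the largest fall among those past the threshold with a mean of at least 2 TPM and no overlap between groups, or the 3 of smallest p where none passed in a direction. It added up to 4 genes past the threshold in each list, and 17 genes named in every case: CCL2, CCL7, CXCL8, CXCL1, CCL20, NFKBIA, TNFAIP3, TLR4, AHR, CYP1A1, CYP1B1, TIPARP, HIF1A, VEGFA, SLC2A1, HK2 and LDHA. Other list members given as examples (AHRR, BCL2L1, CD44, CHAC1, DDIT3, E2F1, LIF, LMCD1, MCM2, NKD1, NQO1, PPP1R15A, PSAT1, RNF43, SAA2, SLC7A5, SP5 and STC2), and values of a gene in a comparison for which the rule did not name it, were chosen after their values were seen. Gene positions are from GENCODE release 29 on GRCh38, matched by Ensembl identifier.

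The overlap and correlation of comparisons that share libraries were set against 100 simulations of unchanged groups. The model was tested on simulated data with 200 changed genes among 12902. For LPS against DMSO it recovered 92.0% of genes raised by 1 on the log2 scale, 30.4% of those raised by 0.5 and 99.8% of those raised by 2, with 5.5% false calls. The simulated noise was drawn from the fitted variances, independently for each gene. These rates therefore leave out differences between libraries that many genes share, and are not error rates of the real data. Alternatives were a pseudocount of 0.1, no filter, a fit of the compared groups alone, the replicate number as a block, a false discovery rate of 0.01, a minimum absolute log2 fold change of 1, and leaving out each library in turn. Median-ratio scaling, quantile normalization, a minimum mean of 5 TPM, removal of the trend with transcript length and GC content, principal transcript lengths in place of the longest ones, and the ribosomal protein share as a covariate were added after the data were seen. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for reading and drawing.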

Results

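The response of SW480 cells, an epithelial line established from a human colorectal adenocarcinoma, to bacterial lipopolysaccharide (LPS) and to indole-3-lactic acid (ILA) was measured by RNA-seq. LPS is an outer-membrane component of Gram-negative bacteria that is sensed through TLR4, and ILA is a tryptophan metabolite made by gut bacteria. The series concerns bacterial ILA and the crosstalk of epithelium and macrophages in intestinal inflammation. There were 9 libraries in 3 groups of 3, all from 6 h of treatment: DMSO, LPS at 6 µg/ml, and LPS at 6 µg/ml with ILA at 200 µM (ILA+LPS). The treatment labels do not say whether the LPS and ILA+LPS libraries also received DMSO. A group with ILA and no LPS was not analysed here, so an effect of ILA on its own cannot be separated from its effect in the presence of LPS. The values are TPM, which scale each library to a fixed total of transcripts and keep no record of sequencing depth, and the depth is unknown. Each library listed between 17899 and 18204 genes above 0, and between 12309 and 12798 genes at 1 TPM or more.

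The libraries were epithelial in most of their marker genes. KRT8 averaged 2685 TPM over the 9 libraries, KRT18 1705, KRT19 1117 and EPCAM 187. Lower means were those of CDX2 (38.17), CDH1 (17.05), VIL1 (1.64) and CDX1 (0.01). Macrophage markers were low, with CD68 at most 5.64 TPM and PTPRC at most 0.05, the highest fibroblast marker was COL1A1 at no more than 2.99, and the 4 endothelial markers in the table stayed at or below 0.87. TLR4 lay between 0.63 and 1.11 TPM in the 9 libraries and was too low to be tested. ILA+LPS replicate 3 stood apart from the other libraries. Genes of cytosolic ribosomal proteins made up 25.5% of its listed TPM against 17.1% to 21.1% in the other libraries, mitochondrially encoded genes made up 13.9% against 16.1% to 17.8%, and its first principal component score was 40.8 where the next highest was 14.1.

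**Figure D1:**
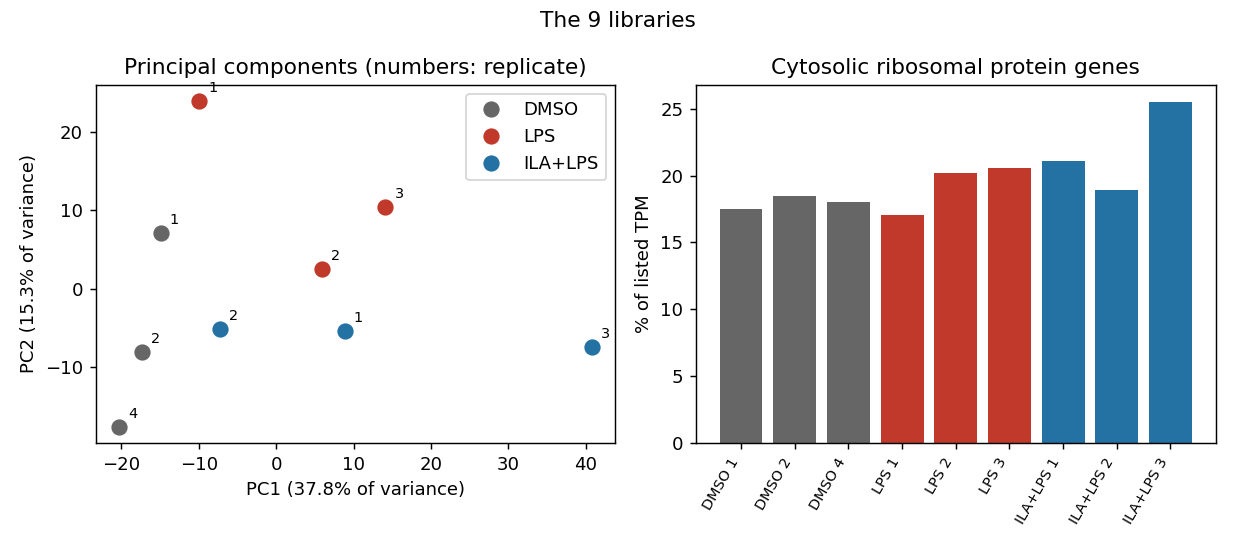
Left, scores of the 9 libraries on the first and second principal components of log2(TPM + 1), coloured by group and numbered by replicate; right, the percentage of listed TPM in cytosolic ribosomal protein genes in each library. ILA+LPS replicate 3 has a first component score of 40.8 and a ribosomal protein share of 25.5%, the highest of the 9 in both.

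The first comparison asked which genes respond to LPS in these cells. The chemokine genes CCL7 and CCL20 had the largest log2 fold changes on the log2(TPM + 1) scale among the genes that passed. By the ratio of mean TPM CCL7 was 15.1-fold higher and CCL20 6.98-fold, below SERPINB2 (14.8-fold) and BCL2A1 (9.3-fold), which lay under 1 TPM in DMSO. CCL7, which encodes a monocyte chemoattractant (chromosome 17, 34270221 to 34272242 in GRCh38), rose from 1.53 ± 0.96 TPM (SD, n = 3) in DMSO to 23.1 ± 4.9 (SD, n = 3) in LPS, a log2 fold change of 3.30 with a standard error of 0.29 (limma, adjusted p = 0.000368). CCL20, the ligand of the chemokine receptor CCR6 (chromosome 2, 227805739 to 227817564), rose from 5.82 ± 0.48 to 40.6 ± 1.1 TPM (SD, n = 3 each), a log2 fold change of 2.61 (SE 0.17, limma adjusted p = 5.55e-05). CCL2, which lies beside CCL7, was 2.14-fold higher in mean TPM (3.38 to 7.21) and did not pass (log2 fold change 0.90, limma adjusted p = 0.0793). In all, 25 of 12902 genes changed at a false discovery rate of 0.05, 20 higher and 5 lower.

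Genes controlled by the transcription factor NF-kB rose with LPS. Of the 31 members of this list that were tested, 5 rose over all genes and 19 rose and 1 fell, BCL2L1, when adjusted over the list alone (median log2 fold change 0.35, camera adjusted p = 2.19e-31). The list passed with an estimated correlation as well (adjusted p = 0.0385). TNIP1, a negative regulator of NF-kB signalling, went from 131 to 314 TPM, the adhesion molecule ICAM1 from 99.9 to 214, TNFAIP2 from 192 to 332 and the antibacterial siderophore-binding protein LCN2 from 401 to 532. The inhibitors NFKBIA and TNFAIP3 were 1.28-fold and 1.42-fold higher and did not pass over all genes (limma adjusted p = 0.311 and 0.323). Among 21 cytokine and chemokine genes 2 rose over all genes and 4 when adjusted over the list alone, CCL20, CCL7, CCL2 and LIF (camera adjusted p = 1.39e-09; adjusted p = 0.0385 with an estimated correlation), while the list median was 0.03. CXCL8 and CXCL1, which encode neutrophil chemoattractants, had log2 fold changes of 0.55 and 0.15 and did not pass (limma adjusted p = 0.399 and 0.679).

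**Figure D2:**
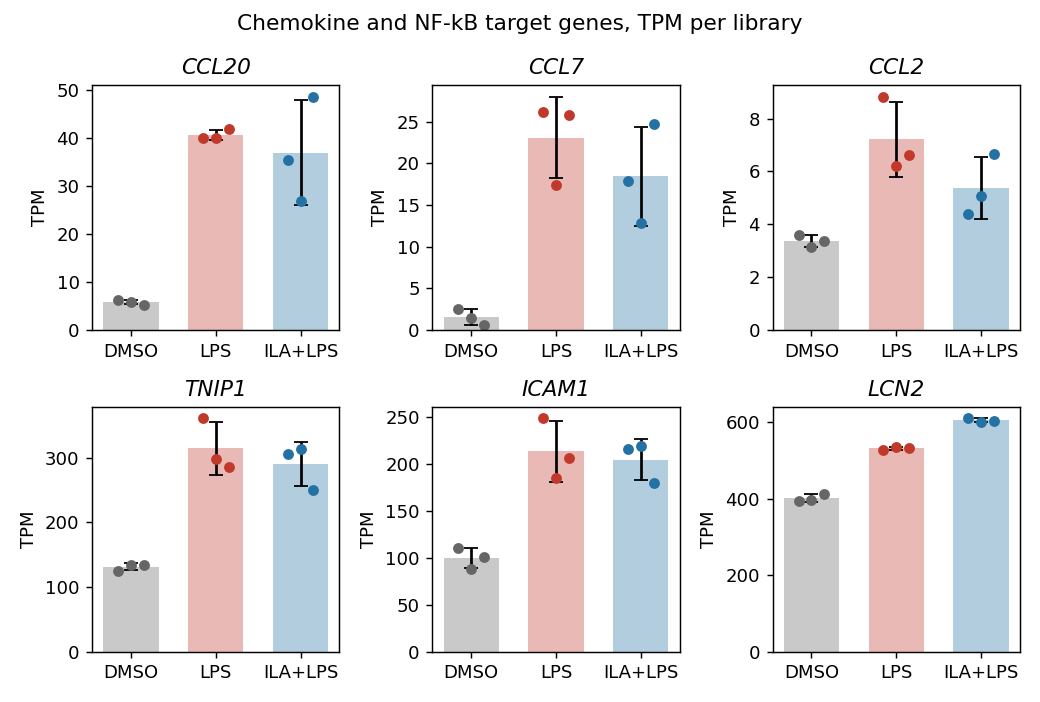
TPM of 6 chemokine and NF-kB target genes; bars are group means, error bars are SD and points are the 3 libraries of each group, on axes that start at 0. CCL20 averaged 5.82 TPM in DMSO, 40.6 in LPS and 37.0 in ILA+LPS, and CCL7 averaged 1.53, 23.1 and 18.5.

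Other genes that rose with LPS included BCL2A1, an anti-apoptotic BCL2 family member (0.67 to 6.23 TPM), ICAM4 (1.81 to 10.9), the elastase inhibitor PI3 (2.13 to 7.34), the epidermal genes SPRR2D (1.54 to 6.51), SBSN (1.82 to 5.37) and KRTAP2-3 (25.8 to 69.8), and the metallothionein MT2A (7247 to 11910 TPM). SPRR2D, KRTAP2-3 and MT2A belong to families of near-identical genes, so their values depend on how RSEM shared reads among copies. The 5 genes that fell were GDF15 (19.2 to 9.01 TPM), ABHD6 (34.6 to 17.7), TRIB3 (47.7 to 25.6), ANKRD1 (348 to 197) and the glutamine transporter SLC1A5 (806 to 546).

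Targets of the aryl hydrocarbon receptor (AhR), a ligand-activated transcription factor that senses indoles and other aromatic compounds, were higher in the LPS libraries. Of 15 members tested 3 rose over all genes, and 8 rose and 1 fell when adjusted over the list alone (median 0.36, camera adjusted p = 4.41e-18; adjusted p = 0.0385 with an estimated correlation). CYP1A1, a cytochrome P450 that is a classical AhR target (chromosome 15, 74719542 to 74725610), rose from 0.60 ± 0.05 to 2.17 ± 0.15 TPM (SD, n = 3 each), TIPARP from 30.7 ± 3.1 to 54.3 ± 2.4, and SERPINB2 from 0.13 ± 0.03 to 1.87 ± 0.38. LMCD1 was the member that fell, with a log2 fold change of -0.99. CYP1B1 went from 0.28 to 1.41 TPM and did not pass over all genes (limma adjusted p = 0.106). Its DMSO mean rested on replicate 1 at 0.62 TPM, with 0.11 in each of the others, and without that library it passed (adjusted p = 0.0475). AHR itself was 15.1 TPM in DMSO and 14.5 in LPS (limma adjusted p = 0.913). TPRA1 showed the same course with a log2 fold change of 1.06 (SE 0.09, limma adjusted p = 0.000368).

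Among 29 targets of ATF4, the transcription factor of the amino acid response, 1 fell over all genes (TRIB3), and 13 fell and 2 rose when adjusted over the list alone (median -0.28, camera adjusted p = 0.00062; adjusted p = 0.659 with an estimated correlation), with log2 fold changes of -0.56 for PSAT1 and -0.81 for CHAC1. Among 18 Wnt target and intestinal stem cell genes none passed over all genes with limma, and 9 fell and 1, CD44, rose when adjusted over the list alone (median -0.40, camera adjusted p = 0.0017; adjusted p = 0.821 with an estimated correlation), with -0.84 for SP5 and -0.82 for RNF43. The HIF target list did not pass (camera adjusted p = 0.169) and neither did glycolysis (0.324). VEGFA had a log2 fold change of -0.57, HIF1A -0.19, SLC2A1 -0.16, HK2 -0.19 and LDHA -0.11, with limma adjusted p from 0.227 to 0.714.

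At an unadjusted p under 0.05 there were 215 genes higher and 1230 lower, around a median log2 fold change of all genes of -0.12. After scaling by median ratios that median was -0.02 and the numbers were 612 and 876, with 62 genes changed at the false discovery rate of 0.05. The count of 25 was 12 without DMSO replicate 4, 13 without DMSO replicate 2, 14 without LPS replicate 1 and 56 without ILA+LPS replicate 3, which enters through the shared estimate of the spread. At the threshold of 0.05 the calls of CCL20, CCL7, TNIP1, ICAM4, TNFAIP2, KRTAP2-3 and TPRA1 held in every refit, while those of ICAM1, BCL2A1, SPRR2D, TIPARP and SERPINB2 ended in 1 refit each, and those of CYP1A1, PI3, SBSN, MT2A, LCN2 and the 5 lower genes in 3 or more.

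The second comparison, ILA+LPS against LPS, asked what ILA changed in the presence of LPS. TIPARP and TPRA1 were the genes that passed, both lower with ILA. TIPARP encodes a mono-ADP-ribosyltransferase that is induced by AhR and represses it (chromosome 3, 156673235 to 156706770). It fell from 54.3 ± 2.4 TPM (SD, n = 3) to 26.9 ± 2.1 (SD, n = 3), a log2 fold change of -0.99 with a standard error of 0.10 (limma, adjusted p = 0.00485). TPRA1 (chromosome 3, 127571266 to 127598267) fell from 92.6 ± 3.0 to 50.01 ± 4.23 TPM, a log2 fold change of -0.88 (SE 0.09, limma adjusted p = 0.00485). Both had risen with LPS, and in ILA+LPS their means, 26.9 and 50.01 TPM, compared with 30.7 and 43.9 in DMSO. No gene was higher at the threshold with limma (195 at an unadjusted p under 0.05).

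The AhR target list was lower in ILA+LPS than in LPS. Of its 15 members 1 fell over all genes, and 10 fell and 1, LMCD1, rose when adjusted over the list alone (median -0.56, camera adjusted p = 6.03e-14; adjusted p = 0.165 with an estimated correlation, 0.00567 with fry). CYP1A1 went from 2.17 to 0.67 TPM (log2 fold change -0.93, limma adjusted p = 0.124), CYP1B1 from 1.41 to 0.12 (-1.10, adjusted p = 0.146), SERPINB2 from 1.87 to 0.55 (-0.89, adjusted p = 0.178), and AHRR had a log2 fold change of -0.89 (adjusted p = 0.425). These members did not pass over all genes. In each of the 4 genes CYP1A1, CYP1B1, TIPARP and SERPINB2 the 3 LPS libraries lay above the 3 ILA+LPS libraries. Groups that did not overlap, in either direction, were seen in 9.63% of all genes, where chance gives 10%, and SERPINB2 was chosen after its values were seen. Of the 15 members, NQO1, SLC7A5 and STC2 are also on another list. The 12 others had a median of -0.52 (camera unadjusted p = 2.86e-11; unadjusted p = 0.00708 with an estimated correlation). AHR was 14.5 TPM in LPS and 11.03 in ILA+LPS (log2 fold change -0.37, limma adjusted p = 0.82).

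**Figure D3:**
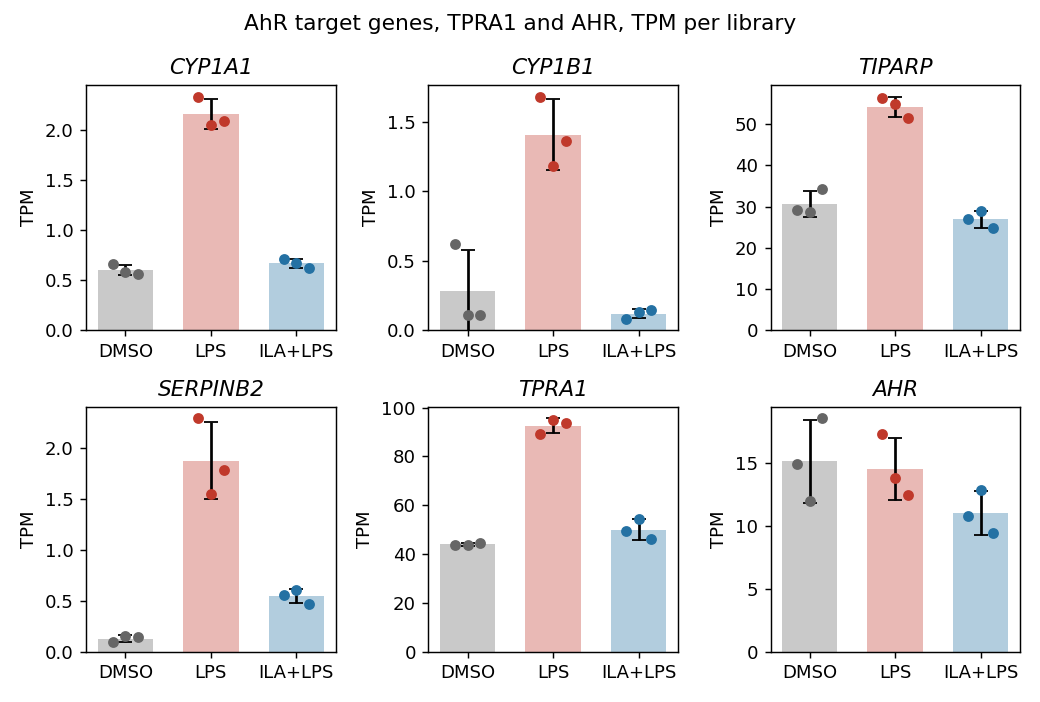
TPM of 4 AhR target genes, TPRA1 and AHR; bars are group means, error bars are SD and points are the 3 libraries of each group, on axes that start at 0. TIPARP averaged 30.7 TPM in DMSO, 54.3 in LPS and 26.9 in ILA+LPS, and CYP1A1 averaged 0.60, 2.17 and 0.67; the SD of CYP1B1 in DMSO exceeds its mean, so its lower error bar ends at 0.

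None of the chemokine and NF-kB target genes raised by LPS passed between ILA+LPS and LPS. CCL7 had a log2 fold change of -0.33 (95% confidence interval -0.96 to 0.29), CCL20 -0.17 (-0.55 to 0.21), CCL2 -0.37 (-0.74 to 0.01), TNFAIP3 -0.08 and NFKBIA -0.004 (limma adjusted p from 0.82 to 0.994). The small differences of CCL20, TNFAIP3 and NFKBIA changed sign in some refits, TNFAIP3 and NFKBIA under median-ratio scaling among them. None of the 31 NF-kB targets passed with limma, over all genes or when adjusted over the list alone. Their median was -0.04, their mean 0.01, and camera, which compares them with all other genes, placed them higher (adjusted p = 0.0454; adjusted p = 0.736 with an estimated correlation). After median-ratio scaling their median was 0.05, and the mean level of the list lay between 0.11 and 0.12 in the LPS libraries and between 0.17 and 0.24 in the ILA+LPS libraries, without overlap. Among the 20 genes that rose with LPS, 14 had a log2 fold change below 0 in ILA+LPS against LPS, from -1.38 to 0.57 with a median of -0.14. All 5 that fell with LPS had values above 0, from 0.17 to 0.39. The LPS libraries enter both comparisons, which by itself pulls such values apart in sign.

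Some neutrophil chemokines had values above 0 without passing. CXCL2 was 10.4 TPM in LPS and 18.1 in ILA+LPS (log2 fold change 0.74, limma adjusted p = 0.29) and was the gene of smallest p among those higher, followed by RASGRP2 (adjusted p = 0.425) and FGF3 (0.552), also not passing. CXCL2 passed when adjusted over the list alone, as 1 of 21 cytokine genes (camera adjusted p = 0.00108 for the list; adjusted p = 0.482 with an estimated correlation). CXCL8 had a log2 fold change of 0.55 and CXCL1 0.30 (limma adjusted p = 0.82 for both). KRTAP2-3, raised by LPS, was 69.8 and 43.1 TPM (adjusted p = 0.325). The HIF target list was higher by camera (adjusted p = 0.0227; adjusted p = 0.736 with an estimated correlation) around a median of 0.01, and none of its members passed with limma. VEGFA had 0.23, HIF1A -0.24, SLC2A1 -0.48, HK2 -0.10 and LDHA 0.14, with limma adjusted p of 0.82 or more.

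All 34 genes of G2/M and mitosis had log2 fold changes below 0 (median -0.31, camera adjusted p = 3.45e-12), as did all 32 of S phase (median -0.23, camera adjusted p = 1.09e-07), and 74 of 75 ribosomal protein genes lay above 0 (median 0.17, camera adjusted p = 6.33e-29). No member of these lists passed with limma when adjusted over the list alone, and with an estimated correlation each had an adjusted p = 0.736. ILA+LPS replicate 3, which held 25.5% of its TPM in ribosomal protein genes, lay 0.45 below the mean of replicates 1 and 2 in the G2/M median. The median deviation of all genes in that library was -0.275, so part of this goes with a shift of all genes. Without ILA+LPS replicate 3 the medians were -0.16 for G2/M, -0.16 for S phase and 0.06 for ribosomal proteins. The ribosomal protein median also depended on LPS replicate 1, without which it was 0.08.

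Of 12902 genes 2 changed by limma. At an unadjusted p under 0.05 there were 665, or 5.15% of all genes, about the share that this level gives without any effect. Of the 665, 195 were higher and 470 lower, around a median log2 fold change of all genes of -0.07. This balance was not stable: the numbers were 540 higher and 345 lower after median-ratio scaling (median 0.01), 449 and 246 without ILA+LPS replicate 3 (median 0.01), and 277 and 1534 without ILA+LPS replicate 2 (median -0.14). Both calls ended without ILA+LPS replicate 1, where TIPARP had a log2 fold change of -0.99 and TPRA1 -0.87 (limma adjusted p = 0.0509 for both; 0.00293 to 0.0509 over all refits). Without ILA+LPS replicate 2 the count was 4, and after median-ratio scaling 6 genes were lower and 0 higher. Across genes the log2 fold changes of LPS against DMSO and of ILA+LPS against LPS had a Pearson r of -0.40 and a covariance of -0.022, where unchanged groups simulated with the same shared LPS libraries gave -0.50 and -0.017. Genes are not independent replicates, and the simulations leave out differences between libraries that many genes share. The 2 genes called in opposite directions compare with a mean of 0.01 in the simulations and with 0.0031 for independent lists. The first value leaves out the effects and the second the shared LPS libraries. Neither says how many such genes the sharing alone would give.

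The third comparison, ILA+LPS against DMSO, asked how cells given both differed from cells given DMSO. CCL7 and CCL20 again had the largest log2 fold changes among the genes that passed, while by the ratio of mean TPM BCL2A1 (9.9-fold) and SPRR2D (6.65-fold) lay above CCL20 (6.36-fold). CCL7 rose to 18.5 ± 6.0 TPM (SD, n = 3; log2 fold change 2.97, SE 0.29, limma adjusted p = 0.000836) and CCL20 to 37.0 ± 11.004 (SD, n = 3; 2.44, SE 0.17, limma adjusted p = 0.000118). TNIP1 reached 290 TPM, ICAM1 205, TNFAIP2 333, LCN2 606, BCL2A1 6.63, ICAM4 8.68, PI3 9.04, SPRR2D 10.3 and SBSN 7.52. ROBO4 rose from 1.10 to 3.66 TPM (limma adjusted p = 0.00451), and in LPS without ILA it was 2.63 (adjusted p = 0.0631 against DMSO). ARHGAP33 was the gene that fell, from 7.80 to 2.89 TPM (log2 fold change -1.16, limma adjusted p = 0.0263). In all 15 genes changed, 14 higher and 1 lower, and 12 were also called in the same direction in LPS against DMSO. Independent lists would share 0.0221 genes and unchanged groups simulated with the same DMSO libraries 0.06. The first leaves out the shared libraries and the second the effects, so part of the excess of shared calls may come from the shared DMSO libraries. The covariance of the log2 fold changes was 0.039 against a simulated 0.017. The simulated noise was independent for each gene, so differences between libraries that many genes share could also move this covariance.

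Of 31 NF-kB targets 5 rose over all genes, and 15 rose and 1, BCL2L1, fell when adjusted over the list alone (median 0.35, camera adjusted p = 1e-33; adjusted p = 0.0494 with an estimated correlation). SAA2, an acute-phase protein, was the fifth of them. Among 21 cytokine genes 2 rose over all genes and 8 when adjusted over the list alone (median 0.28, camera adjusted p = 2.68e-18; adjusted p = 0.0146 with an estimated correlation). CXCL8 was 6.07 TPM in DMSO and 14.6 in ILA+LPS and missed the threshold over all genes (log2 fold change 1.10, limma adjusted p = 0.0851), as did CXCL2 (0.71, 0.158), CCL2 (0.53, 0.172) and CXCL1 (0.44, 0.172). NFKBIA had 0.35 and TNFAIP3 0.37 (limma adjusted p = 0.172 for both), and MT2A 0.62 (0.0563). The AhR target list did not pass against other genes by camera (median -0.18 where that of all genes was -0.19, adjusted p = 0.627), and no member passed when adjusted over the list alone. Fry with mixed directions gave an adjusted p = 0.0189 for the list, so a difference of members both ways is not excluded. This value is not particular to the AhR list. By the same test tryptophan metabolism (0.0189), the TCA cycle (0.0303) and epithelial markers (0.0303) also passed, while others, such as the proteasome (0.233), did not. SERPINB2 was 0.13 TPM in DMSO and 0.55 in ILA+LPS, without overlap between the libraries. TIPARP had a log2 fold change of -0.18 (95% confidence interval -0.41 to 0.05), which turned to 0.02 after median-ratio scaling, TPRA1 0.18, CYP1A1 0.06, CYP1B1 -0.17 and SERPINB2 0.46, with limma adjusted p from 0.172 to 0.794. AHR was -0.41, HIF1A -0.43, SLC2A1 -0.64, VEGFA -0.34, HK2 -0.29 and LDHA 0.03, and none passed.

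Several lists were lower in ILA+LPS than in DMSO when adjusted over the list alone, with no member passing over all genes. S phase genes fell in 24 of 32 members (median -0.43, camera adjusted p = 6.74e-09; adjusted p = 0.746 with an estimated correlation), with -0.57 for MCM2 and -0.63 for E2F1. ATF4 targets fell in 19 of 29 (median -0.33, camera adjusted p = 7.04e-05; adjusted p = 0.664 with an estimated correlation), with -0.57 for PSAT1. Cholesterol synthesis genes fell in 12 of 25 (median -0.28, camera adjusted p = 0.00014; adjusted p = 0.664 with an estimated correlation). The 75 ribosomal protein genes were all above 0 (median 0.27, camera adjusted p = 1.18e-62; adjusted p = 0.234 with an estimated correlation), and ILA+LPS replicate 3 held the highest share of them. Without it the median was 0.15. The median log2 fold change of all genes was -0.19, with 275 genes higher and 2906 lower at an unadjusted p under 0.05. After median-ratio scaling these were -0.01, 998 and 972, and 44 genes changed. Relative to the median of all genes the S phase list lay at -0.23, and at -0.13 without DMSO replicate 1 and -0.35 without DMSO replicate 4. On the same footing the ATF4 list lay at -0.136 and the cholesterol list at -0.087, so part of their falls goes with the shift of all genes.

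**Figure D4:**
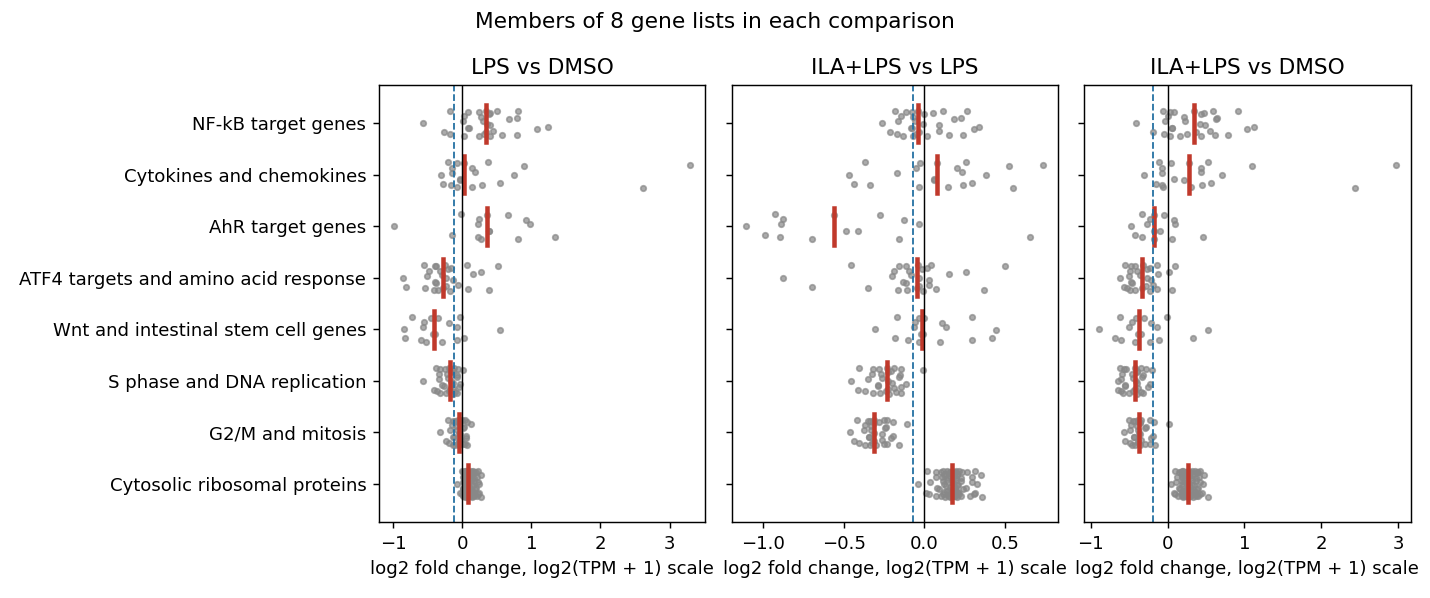
Log2 fold changes on the log2(TPM + 1) scale of the members of 8 gene lists in the 3 comparisons, one point per gene and a red bar at each list's median; the dashed line is the median of all genes and the horizontal scales differ between panels. The AhR list has medians of 0.36, -0.56 and -0.18, and the NF-kB list 0.35, -0.04 and 0.35.

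The count of 15 was 1860 without ILA+LPS replicate 2, of which 1713 were lower, and 24 without ILA+LPS replicate 3. The calls of CCL20, CCL7, TNIP1, LCN2, SPRR2D and SBSN held in every refit, those of ICAM1, TNFAIP2 and ROBO4 ended in 1 refit each, those of BCL2A1 and ICAM4 in 2, PI3 in 4, SAA2 in 5 and ARHGAP33 in 10 of 18.

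The remaining lists gave less. By camera in LPS against DMSO, genes of nuclear-encoded oxidative phosphorylation (adjusted p = 1.29e-13), cytosolic ribosomal proteins (4.41e-18), ribosome biogenesis (1.65e-07), the proteasome (5.6e-06), metallothioneins (0.0017), interferon-stimulated genes (0.0018) and NRF2 targets (0.00389) were higher and S phase lower (0.0294), and none of these passed with an estimated correlation (adjusted p from 0.136 to 0.943). The interferon and NRF2 lists had medians of -0.002 and 0.001, higher than the median of all genes (-0.12) but not away from 0. The S phase call rested on DMSO replicate 1, without which camera gave an adjusted p = 0.978 and the list median lay 0.06 above that of all genes, where it had lain 0.06 below. In ILA+LPS against LPS camera called oxidative phosphorylation (0.000209), TGF-beta and EMT (0.00412) and Wnt genes (0.033) higher, and cholesterol synthesis (0.000124), the TCA cycle (0.00974), mitochondrially encoded genes (0.019), the proteasome (0.0275), fatty acid synthesis (0.0378) and NRF2 targets (0.0388) lower, again with none passing with an estimated correlation. The 16 lists passing there were 7 without LPS replicate 3 and 10 without ILA+LPS replicate 2, and without ILA+LPS replicate 3 oxidative phosphorylation was called lower (camera adjusted p = 0.00462). Wnt genes there had a median of -0.01 and a mean of 0.05. In ILA+LPS against DMSO it called oxidative phosphorylation (8.45e-23), metallothioneins (0.000147), interferon-stimulated genes (0.000239) and ribosome biogenesis (0.00591) higher and G2/M lower (5.34e-05), none with an estimated correlation. There the interferon list had a median of -0.02 and ribosome biogenesis one of -0.03, below 0 but above the median of all genes. The lists of TLR signalling, the AhR complex, tryptophan metabolism, PPAR targets, ER chaperones, immediate early genes, heat shock, p53 targets, tight junctions and mucins, autophagy, replication-dependent histones, glucocorticoid and circadian genes and epithelial markers passed in none of the 3 comparisons with camera.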

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

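The comparison with the NF-kB list, the share of the 10 highest genes and the use of principal transcript lengths were tests chosen only after the result was seen, and median-ratio scaling and the removal of the length and GC trend were added after the data were seen.

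TIPARP and TPRA1 rose with LPS and were lower in ILA+LPS than in LPS, by the direct test between these groups. The log2 fold change of ILA+LPS against LPS was -0.987 for TIPARP and -0.879 for TPRA1. Without a group given ILA alone, a changed response to LPS cannot be told from an effect of ILA that does not need LPS. In a wider pattern, the AhR list level (mean of its members after median-ratio scaling, relative to the 9 libraries) lay between 0.278 and 0.332 in LPS, between -0.186 and -0.128 in DMSO and between -0.155 and -0.117 in ILA+LPS.

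The tables argue against 4 explanations as the whole of the AhR pattern. The list's median in ILA+LPS against LPS, -0.557, was -0.432 or lower in each fit that left out an LPS or ILA+LPS library. Leaving out a DMSO library cannot change it. The median was -0.466 after removal of the trend with transcript length and GC content (-0.463 with the lengths of principal transcripts), and -0.464 after median-ratio scaling. A weaker response to LPS as a whole would lower NF-kB targets too, and their median was -0.039 (95% bootstrap interval over genes -0.074 to 0.057). This interval does not measure the spread between libraries. Of the 20 genes raised by LPS 14 lay below 0 in ILA+LPS against LPS and 6 above, in comparisons that share the LPS libraries. Handling that differed between the groups stays open, including which of them received DMSO. Also open is the hypothesis that ILA may lower AhR target genes in LPS-treated cells without lowering NF-kB targets. A group with ILA alone or cells lacking AHR would test it. The level of the NF-kB list on the scale above was higher in ILA+LPS (0.167 to 0.238) than in LPS (0.105 to 0.123). Of the 10 splits of the 6 libraries, 3 gave at least the 2 changed genes of the real split, the highest of the others gave 2, and so few splits cannot give a share under 0.05. At an unadjusted p under 0.05 the real split gave 665 genes and the others between 188 and 2740.

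ILA+LPS replicate 3 stood apart with a high share of ribosomal protein TPM. A few genes taking most of the total is argued against, since its 10 highest genes held 14.3% of its TPM and those of other libraries up to 16.4%. A preference for short transcripts and a change in ribosomal protein mRNA cannot be told apart: genes that are not ribosomal, matched on level and on the length of their principal (APPRIS) transcripts, rose by 0.174 against replicates 1 and 2 (95% bootstrap interval 0.076 to 0.251) where ribosomal protein genes rose by 0.349, and the interval includes the dividing value set for the test. The test was first run with the longest transcript of each gene, and the matched genes then rose by 0.02 (-0.037 to 0.072), which alone would have argued against short transcripts. That match used lengths far above those of the main transcripts, since the longest transcripts of ribosomal protein genes have a median of 1857 bases and their principal transcripts one of 881. Set above the median of all genes, which was -0.275, the matched genes lay at 0.448 by principal length and 0.295 by longest length, against 0.624 for ribosomal protein genes. Across genes, which are not independent replicates, the library's deviation from replicates 1 and 2 had a Spearman correlation of -0.525 with principal and -0.467 with longest transcript length. Such a correlation was not confined to this library. With longest length, each library against the rest of its group, it was 0.432 in ILA+LPS replicate 2 and 0.311 in LPS replicate 1. In LPS replicate 3 it was -0.274, and in the remaining libraries it lay between -0.133 and 0.153. ILA+LPS replicate 2 is part of the mean that replicate 3 was set against.

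The S phase list had a median of -0.427 in ILA+LPS against DMSO (camera adjusted p = 6.74e-09). It did not pass with an estimated correlation (camera adjusted p = 0.746) or with fry (adjusted p = 0.0942). For this pattern 2 explanations were tested, each with a bound of -0.1. Neither test decides, because the outcome turns on the spread chosen. Closure of the TPM total by the ribosomal share moves all genes alike, and after median-ratio scaling the list's median was -0.219 (1 standard error between libraries, -0.318 to -0.12; bootstrap over genes, -0.331 to -0.183). For the gradient that replicate 3 shows most, the scaled median without that library was -0.233 (-0.343 to -0.123; bootstrap, -0.289 to -0.175). With 2 standard errors the intervals reach -0.021 and -0.012, past the bound, so the narrower spreads alone would argue against the 2 explanations. Leaving out replicate 3 also cannot exclude a gradient that other libraries share. The spread was changed more than once after the values were seen. Both explanations stay open, as do variation between libraries of a group and a difference in proliferation. The level of the list ranged from -0.083 to 0.292 within DMSO and from -0.157 to -0.088 in ILA+LPS. Without DMSO replicate 1 its median relative to all genes was -0.127.

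For LPS against DMSO the real split gave 25 changed genes and the highest of the other splits 3, so that 1 of 10 gave as many. For ILA+LPS against DMSO the real split gave 15 and the highest of the others 3, again 1 of 10. With 10 splits no share under 0.05 can be reached.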

How the results depend on the processing

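Median-ratio scaling, quantile normalization, a minimum mean of 5 TPM, removal of the length and GC trend, the ribosomal protein share as a covariate and array weights were chosen after seeing the data. Array weights were not used: their estimation did not converge, gave ILA+LPS replicate 1 a weight of 107 against 0.115 to 1.71 for the others, and led to 1750, 2005 and 6880 changed genes in LPS against DMSO, ILA+LPS against LPS and ILA+LPS against DMSO; they were dropped after this was seen. The alternatives that need read counts (DESeq2, limma-voom, other size factors and filters on CPM) were not run because the table holds TPM, to which no composition scaling had been applied. Of 2477 values of single genes and lists under the alternatives, 2145 kept their direction and side of the threshold, 219 were no longer past it, 76 newly passed and 37 changed sign. For the changes below the cause was not tested, except that stricter thresholds lower a count by construction. TPM keeps no depth, so the counting error of low genes cannot be given.

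TIPARP and TPRA1 were called lower in ILA+LPS than in LPS in every refit at a false discovery rate of 0.05 except without ILA+LPS replicate 1. Requiring an absolute log2 fold change of at least 1 left 14 genes in LPS against DMSO and 0 in ILA+LPS against LPS (limma; 665 genes at an unadjusted p under 0.05). A false discovery rate of 0.01 left 14 in LPS against DMSO. Without a filter 11, 4 and 8 genes changed in the 3 comparisons in the order above, and fits of only the compared groups gave 45 in LPS against DMSO and 4 in ILA+LPS against LPS. With an estimated correlation 3, 0 and 2 gene lists passed and with fry 3, 1 and 4; fry placed interferon-stimulated genes (adjusted p = 0.78) and ribosome biogenesis (0.706) lower in ILA+LPS against DMSO.

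Leaving out each library in turn gave 12 to 56 changed genes in LPS against DMSO, 0 to 4 in ILA+LPS against LPS and 12 to 1860 in ILA+LPS against DMSO, the last without ILA+LPS replicate 2. The lists passing were 12 to 15, 7 to 19 and 11 to 13, the LPS-changed genes called in the opposite direction with ILA 0 to 3, and the correlation of the log2 fold changes -0.533 to -0.266. Log2 fold changes that crossed 0 ranged, in LPS against DMSO, from -0.196 to 0.101 for AHR (0.05 without LPS replicate 3), from -0.312 to 0.011 for SLC2A1 and from -0.211 to 0.032 for LDHA. In ILA+LPS against LPS they ranged from -0.073 to 0.051 for NFKBIA (0.011 without LPS replicate 2, 0.044 without ILA+LPS replicate 3), from -0.384 to 0.034 for CCL20 and from -0.205 to 0.049 for HK2. Oxidative phosphorylation there had camera adjusted p from 2.91e-17 to 0.737 and was called lower (adjusted p = 0.00462) without ILA+LPS replicate 3. In ILA+LPS against DMSO they ranged from -0.071 to 0.172 for LDHA (-0.003 without DMSO replicate 2, -0.049 without ILA+LPS replicate 2) and from -0.264 to 0.008 for CYP1B1.

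Median-ratio scaling gave 62, 6 and 44 changed genes and 4 called in opposite directions, with log2 fold changes of AHR 0.06 and LDHA 0.008 (LPS against DMSO), NFKBIA 0.091 and TNFAIP3 0.009 (ILA+LPS against LPS) and TIPARP 0.023 (ILA+LPS against DMSO). Quantile normalization gave 69, 8 and 47, with 5 opposite, and AHR 0.1, NFKBIA 0.079, TNFAIP3 0, LDHA -0.084 and TIPARP 0.008 in the same comparisons, LDHA against DMSO with ILA. Removal of the length and GC trend gave 95, 7 and 55, with 5 opposite, and AHR 0.122, TNFAIP3 0.018, CYP1B1 0.079 and TIPARP 0.055, the last 2 in ILA+LPS against DMSO. The ribosomal protein share as a covariate gave 81 in LPS against DMSO, with AHR 0.05 there and NFKBIA 0.078, TNFAIP3 0.021 and HK2 0.076 in ILA+LPS against LPS. TIPARP and TPRA1 were among the genes called in ILA+LPS against LPS under each of these.

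Residual correlations across genes gave no sign that replicate numbers pair the samples. They ran from -0.129 to 0.192 between libraries of the same number and from -0.235 to 0.249 between libraries of different numbers. So few libraries cannot exclude a pairing. With the replicate number as a block 16 genes changed in LPS against DMSO, 14 of them among the 25, and AHR (0.199), SLC2A1 (0.138) and LDHA (0.078) changed sign there. The number 4 occurs in DMSO alone, so the block fits DMSO replicate 4 exactly and takes that library out of the comparison. The same genes changed sign when DMSO replicate 4 was left out. The block gave 2 in ILA+LPS against LPS and 12 in ILA+LPS against DMSO. In ILA+LPS against LPS 305 genes were then higher and 778 lower at an unadjusted p under 0.05 with limma, against 195 and 470 without the block.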

Other observations

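Some gene groups had members that moved against one another. In ILA+LPS against LPS the ATF4 list did not pass as a whole (camera adjusted p = 0.646). Adjusted over the list alone, SLC7A5 (log2 fold change -0.69), STC2 (-0.87) and PPP1R15A (-0.46) fell and DDIT3 (0.50) rose, and SLC7A5 and STC2 are also on the AhR list.

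In ILA+LPS against DMSO 8 of the 18 Wnt target and intestinal stem cell genes fell and 1, CD44 (0.52), rose when adjusted over the list alone with limma, with none passing over all genes. The list did not pass as a whole (median -0.37, camera adjusted p = 0.371). NKD1 (-0.89) and RNF43 (-0.68) had the lowest values of those that fell. The genes named here were chosen after their values were seen.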
